A study of Mus musculus with 5 samples.

How the data were processed

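The series holds 5 anti-BATF ChIP-seq libraries of mouse splenic cells (C57BL/6J, 8 to 12 weeks old, per the labels), and the table used here covers the 4 libraries at 72 h, 2 of WT and 2 of Tet2/3 DKO. No column for the 0 h library was used, so that comparison was not made. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes the tools included bcl2fastq 2.20.0.442, Bowtie 1.1.2, Picard 2.7.1 and HOMER, and the build was mm10 (GRCm38). Their order and settings, the handling of duplicates and the way regions were called are not given in the sources used here.

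The authors deposited, for each region and library, a column headed counts, which is treated here as a score because its values are quantile-normalised counts rounded to whole numbers. All 4 columns reach the same maximum of 586. Quantile normalisation gives the libraries the same distribution and so removes any genome-wide difference in binding between them. The deposited RPKM values, reads per kilobase of region scaled to library depth, predate that step and are rounded to 2 decimals. The authors' deposited table also gives log2 fold changes, WT over DKO, and a p-value and adjusted p-value per region from edgeR, per the file headers. Group means in the deposited table equal the mean of the library columns and were not tested.

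Whole reads were recovered from the RPKM with the region length and a single total per library, the smallest total for which nearly all values came out whole within 0.0051 RPKM. The share of whole values was 100.0%, 99.97%, 100.0% and 100.0% in WT replicates 1 and 2 and DKO replicates 1 and 2, against 12.0%, 5.83%, 9.05% and 12.3% by chance. Totals were 42967000, 20866000, 32386000 and 43981000 reads, of which 2.07%, 2.68%, 2.05% and 2.31% fell in the regions. Each recovered read number corresponded to 1 quantile-normalised value (246 of 246, 177 of 177, 210 of 210 and 267 of 267 read numbers). WT replicate 2 is the shallowest library, and its normalised values carry the most counting error.

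The planned test for raw counts did not apply, so the fallback fixed before the data were examined was used: limma 3.58.1 (trend, R 4.3.3) on log2 of the quantile-normalised count + 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on this scale, which understates the change of weak regions. That plan did not say which normalised value to use, and the quantile-normalised count was chosen over RPKM after both, and several other fits, had been looked at together. No filter on low values was applied, also a choice made after the data were seen. Confidence intervals are 95% intervals from limma. The sum over the Aicda locus was compared by an exact permutation test over the 3 splits of the libraries. Lists were tested with limma's camera (preset correlation 0.01, and an estimated correlation), adjusted over the 12 lists.

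Genes came from a RefSeq table of assembly GRCm38.p6, which matches the build of the regions. It gives gene bodies without strand or exons, so each region was assigned to the nearest protein-coding gene body within 100 kb, where the plan had named the transcription start site, and no exon, intron or promoter is stated. A gene was assigned to 25356 regions (94.2%), and 16637 (61.8%) lay inside a gene. Of 242 list genes, 241 were matched, P2ry8 being the exception. The lists were AID and class switch machinery, regulators of Aicda, IL-4 and STAT6 response, LPS and NF-kappaB response, AP-1 and BATF partner factors, B cell identity, germinal centre B cell, plasma cell, growth, cycle and survival, TET and DNA methylation enzymes, T and NK cell markers, and myeloid and erythroid markers.

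Named regions follow a rule written before the data were examined: all regions within 50 kb of Aicda; called regions in each direction or, with fewer than 5 called, the 5 of smallest p; the 5 with the highest mean; the called members of each list or, with none, its strongest; and the strongest at Tet2 and Tet3. Libraries were compared in pairs before averaging. Chi-square per degree of freedom ran from 1.19 to 1.65, so no library pair agreed within sampling noise. Pearson correlations of log2 values across regions were 0.765 between the WT replicates and 0.818 between the DKO replicates. Between genotypes they ran from 0.752 (WT replicate 2 with DKO replicate 1) to 0.847 (the replicate 1 libraries). The replicate 1 libraries of the 2 genotypes thus correlated more than the replicates of either genotype. Each pair with WT replicate 2 (0.752 to 0.789) correlated less than any pair without it.

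The test was checked on 5 simulated data sets with the real means and library sizes and a dispersion of 0.0265, in which 200 regions per set were changed. That dispersion was re-estimated after a first run with a lower estimate had given higher recovery. Of the regions changed 1.5-fold, 2-fold and 4-fold, the test called 0%, 0% and 18.2% with 0 false calls, and gave the right direction for 91.6%, 98.2% and 100.0%. Limma-voom on simulated reads called 1.19%, 10.1% and 70.6%, with 11 false calls over the 5 sets.

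Alternatives fixed beforehand were scaling of recovered reads by median of ratios or by region totals, filters at a mean of 1 or 20, a pseudocount of 0.1, limma-voom on recovered reads, the replicate number as a block, a threshold of 0.1, merging of adjoining regions, genes within 20 kb, an estimated set correlation, and leaving out each library. Added after seeing the data were RPKM as deposited, limma-voom with the block, and leaving out chromosomes X and Y or the regions of the 4 commonest lengths. Promoter, motif, GC and CpG classes need a genome sequence or strand and were not analysed here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were also used.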

Results

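BATF occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse splenic B cells activated with lipopolysaccharide (LPS, 25 µg/mL) and interleukin-4 (10 ng/mL). BATF is a basic leucine zipper factor of the AP-1 family that binds DNA with Jun partners and, at composite elements, with IRF4 or IRF8. Both genotypes carried floxed Tet2 and Tet3, which encode enzymes that oxidise 5-methylcytosine, and the double knockout (DKO) cells also carried a CreERT2 recombinase. At 72 h there were 2 wild-type (WT) and 2 DKO libraries. A further library came from unstimulated B cells at 0 h and was not analysed here. The deposited table held 26909 regions with a median length of 263 bp. Library totals recovered from the table were 42967000 and 20866000 reads for WT replicates 1 and 2, and 32386000 and 43981000 for DKO replicates 1 and 2. Reads inside the regions numbered 887769, 559030, 663707 and 1015964 in the same order. The median region therefore held 26, 15, 19 and 29 reads, which limits the precision of single regions. The labels do not say which libraries came from separate mice, so p-values measure only the spread between these libraries. Chromosome Y reads differed between replicates 1 and 2 of each genotype, being 540 and 96 in WT and 456 and 154 in DKO.

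The targeted genes were examined first. The strongest region assigned to Tet2 lay 81.5 kb outside the gene, on chromosome 3 from 133626605 to 133626896 (GRCm38). Its quantile-normalised count was 107 ± 1.41 in WT and 102 ± 2.12 in DKO (SD, n = 2 each), a log2 fold change of -0.08 (95% CI -0.40 to 0.25). The region at Tet3, inside the gene body on chromosome 6 from 83442573 to 83442859, had 17.5 ± 7.78 in WT and 17 ± 1.41 in DKO (SD, n = 2 each). Neither difference passed limma's test with Benjamini-Hochberg adjustment over all regions (adjusted p = 0.998 for both). Binding measured outside a deleted exon says nothing about the deletion, and the positions of the floxed exons were not given in the sources used here. These values therefore do not check the genotype labels.

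The first comparison asked whether BATF binding at Aicda depended on Tet2 and Tet3. Aicda encodes AID, the deaminase that starts class switch recombination and somatic hypermutation, and the study title places TET action at its superenhancer. BATF occupied 5 regions within 50 kb of the gene, and the 3 on its lower-coordinate side were far stronger than the other 2. The strongest lay 26.1 kb below the lower-coordinate end of Aicda, inside the body of the neighbouring gene Mfap5 (chromosome 6, 122527621 to 122527878), and ranked 63 of all regions by mean. It had 190 ± 9.19 normalised counts in WT and 170 ± 9.19 in DKO (SD, n = 2 each), a DKO to WT ratio of 0.895 (95% CI 0.747 to 1.07). The region 20.8 kb below Aicda, between Mfap5 and Aicda (122532900 to 122533173), had 88.0 ± 5.66 in WT and 69.5 ± 7.78 in DKO. Both DKO libraries lay below both WT libraries in these 2 regions. The region 8.30 kb below Aicda (122545364 to 122545658) had 118 ± 38.2 in WT and 103 ± 29.7 in DKO. Its values were 145 and 91 in WT and 124 and 82 in DKO, so its replicates differed more than its genotypes.

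On the higher-coordinate side, the region from 122570759 to 122571105, between Aicda and Apobec1, had 24.0 ± 8.49 in WT and 28.5 ± 4.95 in DKO (SD, n = 2 each). The region inside Apobec1 (122602200 to 122602426) had 15 ± 4.24 in WT and 17.5 ± 6.36 in DKO. No region of the locus passed limma's test over all regions, where each had an adjusted p of 0.998, and 0 passed when adjusted over the locus alone, by limma or by limma-voom. The count at an unadjusted p under 0.05 was 0 by limma and 1 by limma-voom on recovered reads (region 20.8 kb below Aicda, unadjusted p = 0.0379, adjusted p = 0.173 over the locus alone). By limma the smallest p was that of the region 20.8 kb below Aicda, with a log2 fold change of -0.34 (95% CI -0.72 to 0.05), unadjusted p = 0.0813 and adjusted p = 0.407 over the locus alone. Its interval runs from a DKO to WT ratio of 0.605 to 1.03. Summed over the locus, normalised counts were 434 ± 36.1 in WT and 388 ± 39.6 in DKO (SD, n = 2 each; two-sided exact permutation p = 0.667, where the smallest possible is 0.333). A 2 against 2 design cannot reach 0.05 in that exact test.

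**Figure D1:**
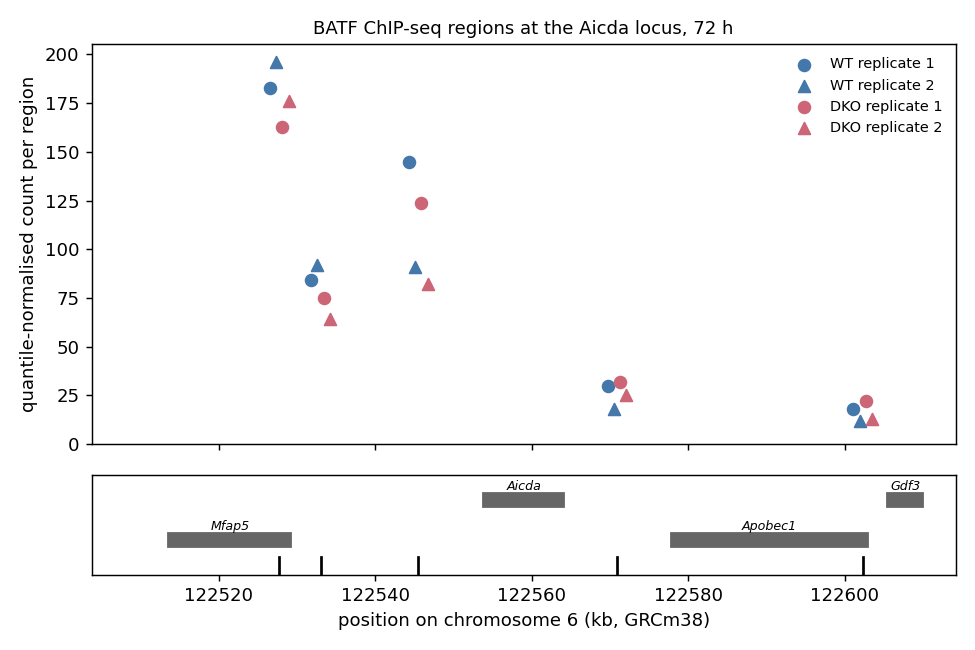
Quantile-normalised BATF counts of the 5 regions within 50 kb of Aicda in each of the 4 libraries (upper panel, points of a region set side by side for legibility), over the gene bodies and region positions on chromosome 6 in kb of GRCm38 (lower panel). WT values of 183 and 196 and DKO values of 163 and 176 mark the strongest region, and in the region 8.30 kb below Aicda the replicates of each genotype spread more than the genotypes do.

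The second comparison covered BATF occupancy across the genome. At 72 h, 0 of 26909 regions differed between DKO and WT by limma at an adjusted p under 0.05, and the smallest adjusted p was 0.998. At an unadjusted p under 0.05 there were 666 regions, or 2.48% of those tested. Of the unchanged regions in the simulated data, 3.97% fell under the same limit by the same test. The 666 are therefore no excess over that simulated share. The simulation held no replicate effect and no regions led by 1 library, so the comparison does not show that differences are absent. The simulated recovery may not hold for the real libraries either. Of the 666, 360 were higher and 306 lower in DKO. That split was not stable. It was 450 and 400 on recovered reads scaled by median of ratios, 490 and 364 by region totals, 105 and 398 on the deposited RPKM, and 285 and 583 by limma-voom, which also changes the test. Leaving out a DKO library turned it, with 124 higher and 337 lower without replicate 1 and 213 and 380 without replicate 2, while it was 485 and 295 without WT replicate 2, and 1125 and 671 without WT replicate 1. The authors' deposited table likewise listed 0 regions at an adjusted p under 0.05, with 360 higher and 355 lower in DKO at an unadjusted p under 0.05 and a smallest adjusted p of 0.897. Limma-voom on recovered reads called 1 region, named here only because it was the single call after the values were seen. It lay inside Pole2, which encodes a DNA polymerase epsilon subunit (chromosome 12, 69213268 to 69213593), with 54 and 23 reads in WT and 22 and 11 in DKO, a log2 fold change of -1.74 and an adjusted p of 0.0226. Limma on the quantile-normalised counts gave it a log2 fold change of -1.37 (-0.57 without DKO replicate 2 and -2.16 without DKO replicate 1) and an adjusted p of 0.998. Over 5 simulated data sets limma-voom made 11 false calls and limma 0. Limma-voom also called more true changes there, 233 of 330 regions changed 4-fold (70.6%) against 60 (18.2%) by limma. The false calls alone therefore do not tell whether the Pole2 call is false. Without WT replicate 1, limma gave 1796 regions at an unadjusted p under 0.05 in place of 666 and still 0 past the threshold.

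The regions with the smallest p in each direction are described by their values, since none passed. Among those higher in DKO, a region on chromosome 17 (4626220 to 4626496) with no gene within 100 kb had 8 and 8 normalised counts in WT and 60 and 18 in DKO. A region 47.3 kb from Sulf1, an extracellular heparan sulfatase gene (chromosome 1, 12644690 to 12644943), had 6.00 ± 2.83 in WT and 28.0 ± 11.3 in DKO (SD, n = 2 each). At Tbl1x, which encodes a corepressor subunit (chromosome X, 77509186 to 77509471), WT had 11 ± 1.41 and DKO 29.0 ± 0.00. Regions next to Isoc1 (chromosome 18, 58659127 to 58659481) and 54.7 kb from Gm5861 (chromosome 5, 11127990 to 11128330) had WT means of 7.50 and 24.5 and DKO means of 25.0 and 47.0. Log2 fold changes of these 5 regions ran from 0.92 to 2.05.

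Among those lower in DKO, a region inside Prrc2b (chromosome 2, 32180072 to 32180392) had 57.0 ± 1.41 in WT and 28.5 ± 10.6 in DKO (SD, n = 2 each). Inside Rgs8, a regulator of G-protein signalling (chromosome 1, 153696174 to 153696452), WT had 80.0 ± 15.6 and DKO 46.5 ± 0.707. A region 9.83 kb from Scd1, a stearoyl-CoA desaturase gene (chromosome 19, 44384404 to 44384618), had 28.5 ± 9.19 in WT and 10.0 ± 0.00 in DKO. Regions 88.7 kb from Sox5 (chromosome 6, 144870987 to 144871247) and 1.33 kb from Fut8, the core fucosyltransferase gene (chromosome 12, 77235786 to 77236099), had WT means of 44.0 and 50.0 and DKO means of 22.0 and 26.5. Unadjusted p in the 10 regions ran from 0.000706 to 0.00293, and every adjusted p was 0.998. In data simulated for this comparison, the test called 0% of regions changed 2-fold and 18.2% of those changed 4-fold, so changes of these sizes were mostly not detectable by this test with these libraries. The region at Scd1 was 215 bp long, a length whose regions were highest in WT replicate 2 in 82.4% of cases.

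**Figure D2:**
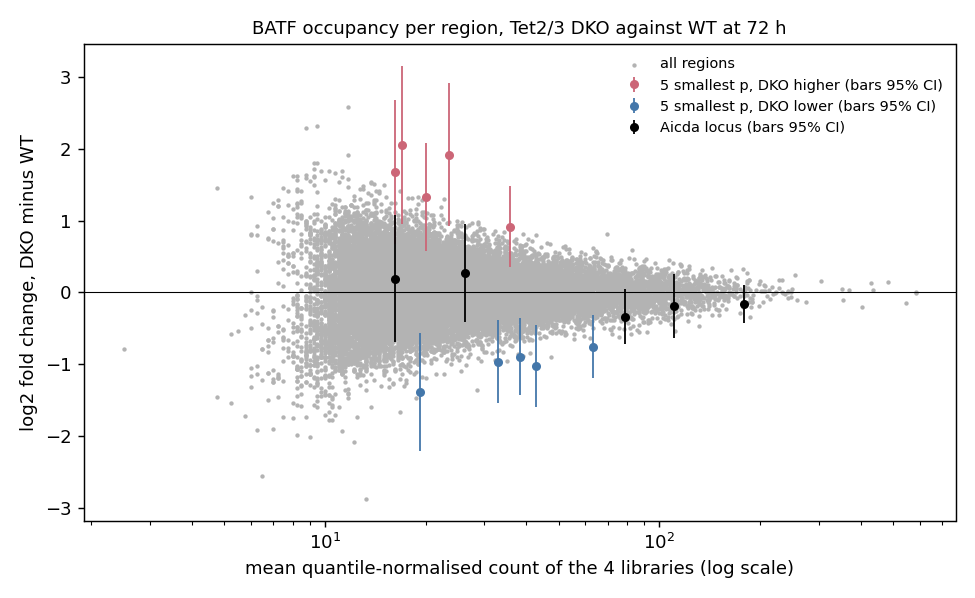
Log2 fold change of each of the 26909 regions, DKO minus WT, against the mean quantile-normalised count of the 4 libraries on a log axis, with 95% confidence intervals (bars) for the 5 regions of smallest p in each direction and the 5 regions at Aicda. The spread narrows with the mean count, and the Aicda intervals all include 0.

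Quantile normalisation gives the same values to the top ranks of every library, so close means among the strongest regions are expected by construction. On chromosome 2, regions from 98666579 to 98666835 and from 98662532 to 98662783, with no gene within 100 kb, had WT means of 586 and 572 and DKO means of 585 and 520. A region 29.3 kb from Rpusd4 (chromosome 9, 35305246 to 35305501) had 583 in WT and 585 in DKO, and one 21.2 kb from Ly6c2 (chromosome 15, 75086704 to 75087011) had 458 and 510. Inside Commd10 (chromosome 18, 46997798 to 46998288) the means were 430.0 and 439. None passed the test (adjusted p = 0.998 for each), and the read numbers of the top 3 hardly followed library depth. Log2 fold changes of these 3 on other scales therefore reflect depth: the region near Rpusd4 had -0.22 on recovered reads scaled by region totals and -0.33 on RPKM, and the 2 on chromosome 2 had -0.22 and -0.22, and -0.33 and -0.33.

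Regions were then grouped by 12 gene lists fixed before the data were examined, which held 242 genes. By limma on the quantile-normalised counts, 0 regions of every list were called higher or lower over all regions tested, and 0 when adjusted over the list alone. At an unadjusted p under 0.05, higher and lower regions in DKO numbered 1 and 3 for B cell identity, 1 and 1 for plasma cells, 3 and 0 for growth, 0 and 1 each for the LPS, IL-4 and T cell lists, 2 and 0 for class switch machinery, 0 and 2 for TET enzymes, and 0 and 0 for myeloid markers. Regulators of Aicda had 219 regions, of which 1 was higher and 5 lower in DKO at an unadjusted p under 0.05. Their strongest region lay inside Bach2, a repressor of plasma cell differentiation (chromosome 4, 32401565 to 32401839), with 166 ± 15.6 in WT and 174 ± 0.707 in DKO (SD, n = 2 each). The same region led the AP-1 and BATF partner list, whose 98 regions had a median log2 fold change of -0.07, with 2 higher and 5 lower at an unadjusted p under 0.05. That list had the smallest set p (limma camera, lower in DKO, p = 0.0317), but it did not pass over the 12 lists (adjusted p = 0.265; adjusted p = 0.641 with an estimated correlation).

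Germinal centre genes had 90 regions, a median of -0.04 and 4 regions lower at an unadjusted p under 0.05, and the list did not pass (camera p = 0.0441, adjusted p = 0.265; adjusted p = 0.641 with an estimated correlation). Their strongest region, 25.9 kb from the histone methyltransferase gene Ezh2 (chromosome 6, 47621142 to 47621408), had 248 ± 13.4 in WT and 248 ± 12.7 in DKO (SD, n = 2 each). The 99 regions of B cell identity genes were led by one inside the lineage factor gene Ebf1 (chromosome 11, 44636309 to 44636564), with 170 ± 10.6 and 164 ± 29.0. Plasma cell genes had 76 regions, led by one inside the elongation factor gene Ell2 (chromosome 13, 75740061 to 75740311) with 166 ± 4.95 and 154 ± 12.0. Camera's adjusted p was 0.513 for B cell identity, 0.300 for plasma cells and 0.284 for regulators of Aicda.

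Of the stimulus-response lists, LPS and NF-kappaB genes had 108 regions, and the strongest lay inside Il10, an anti-inflammatory cytokine gene (chromosome 1, 131022618 to 131022874), with 155 ± 11.3 in WT and 146 ± 29.0 in DKO (SD, n = 2 each). IL-4 and STAT6 genes had 48 regions, led by one 5.51 kb from the chemokine gene Ccl22 (chromosome 8, 94739918 to 94740174) with 72.0 ± 14.1 and 80.5 ± 4.95. The 97 regions of growth and survival genes were led by one inside the cell cycle kinase gene Cdk6 (chromosome 5, 3494788 to 3495042) with 214 ± 5.66 and 195 ± 4.24. Its log2 fold change of -0.13 (95% CI -0.38 to 0.11) did not pass the test. Camera's adjusted p was 0.518 for the LPS and for the IL-4 list and 0.983 for growth and survival.

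Class switch machinery genes had 37 regions with a median of 0.09, and their strongest was the region 8.30 kb below Aicda, described above. In the 21 of these regions outside the 4 commonest lengths the median was -0.05. Of the 33 regions of TET and DNA methylation enzymes, 12 were assigned to Tet2, a gene the design deletes, and the median was -0.07. It was 0.07 in the 20 regions with a mean of at least 20, and -0.18 in the 24 within 20 kb of a gene. Their strongest region, inside the DNA methyltransferase gene Dnmt3a (chromosome 12, 3846260 to 3846510), had 110 ± 7.07 in WT and 125 ± 0.00 in DKO (SD, n = 2 each). Adjusted p by camera was 0.513 and 0.284 for these lists. Markers of other cell types gave 42 regions for T and NK cells, led by Ctla4 (chromosome 1, 60913369 to 60913640; 150 ± 13.4 and 148 ± 13.4), and 24 for myeloid and erythroid cells, led by Itgam (chromosome 7, 128069982 to 128070232; 65.5 ± 10.6 and 71.5 ± 14.8). Both had an adjusted p of 0.983. Camera's direction was up for growth, myeloid and T cell lists although their medians were -0.03, -0.0035 and -0.02, and their means -0.0012, -0.06 and 0.0016. With an estimated correlation no list passed either, the smallest adjusted p being 0.641.

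**Figure D3:**
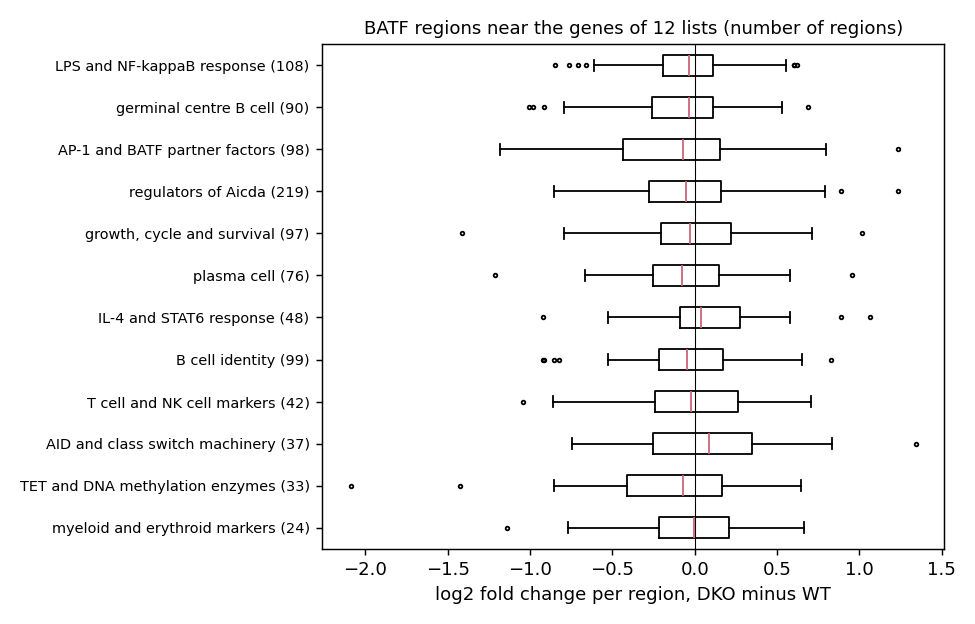
Log2 fold change per region, DKO minus WT, for the regions near the genes of each of the 12 lists (boxes, quartiles with the median in red; whiskers, the farthest values within 1.5 box lengths; points, regions beyond; number of regions in brackets). Every median lies between -0.08 and 0.09, and no list passed the set test.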

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

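The count of 0 regions past an adjusted p of 0.05 held in limma fits on every scaling, filter, pseudocount and left-out library tried, and at a threshold of 0.1 for the quantile-normalised counts. Limma-voom on recovered reads, with 1 call, and its fit with the block were the exceptions. Scaling by region totals gave a smallest adjusted p of 0.0991 and by median of ratios 0.105. At Aicda, 0 regions passed over the locus alone under each alternative run there (merging of adjoining regions was not). Regions at an unadjusted p under 0.05 numbered 666, against 346 with a mean of at least 20 and 378 without the 4 commonest lengths, where fewer regions were tested. Leaving out 1 library gave 461 to 1796, the highest without WT replicate 1, where the lone WT library is assumed to vary like the DKO libraries. Where no cause is given, the cause was not tested. RPKM as deposited, limma-voom with the block, and the fits without X and Y or the commonest lengths were chosen after seeing the data.

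Samples with the same replicate number share only that number in the labels. With the replicate block on quantile-normalised counts 0 regions passed (smallest adjusted p 0.677, 1186 at an unadjusted p under 0.05), 0 passed at Aicda over the locus alone (smallest unadjusted p 0.0470, 20.8 kb below the gene) and no list passed. Deviations of same-numbered libraries from their group means correlated at 0.13 across regions. In the 3 regions below Aicda each DKO value was lower than the WT value of the same number, and over the locus the sums were 460 and 416 for number 1 and 409 and 360 for number 2. Limma-voom with the block gave 0 at Aicda over the locus alone (smallest unadjusted p 0.0179, adjusted p 0.0893), 1444 regions at an unadjusted p under 0.05 and 4 calls, Jun (log2 fold change -1.70, adjusted p 0.0413), Prrc2b (-1.04, 0.0413), Pex14 (-0.97, 0.0422) and the chromosome 17 region without a gene (2.7, 0.00631). Pole2 was not among them (adjusted p 0.234). The Jun region, in the AP-1 and BATF partner list, was 215 bp long, a length highest in WT replicate 2 in 82.4% of cases. Jun and Pex14 are named because they were called, after their values were seen.

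Among the named regions, 457 values kept their direction and side of the threshold, 4 were exactly 0 without a call (the 2 chromosome 2 regions, Rpusd4 and Commd10 without DKO replicate 2), 2 gained a call (Prrc2b and the chromosome 17 region) and 38 changed sign without a call. Log2 fold changes that changed sign under median-of-ratios scaling were -0.23 (Rpusd4), -0.013 (Commd10) and -0.043 (Ezh2); under region totals -0.22 (Rpusd4) and -0.029 (Ezh2); under limma-voom -0.23 (Rpusd4), -0.0073 (Commd10) and -0.040 (Ezh2); under limma-voom with the block -0.23 (Rpusd4), -0.012 (Commd10), -0.041 (Ezh2) and -0.062 (Tet3). On RPKM they were -0.33 (Rpusd4), -0.072 (Ly6c2), -0.11 (Commd10), -0.062 (Bach2), -0.14 (Ezh2), -0.027 (Itgam) and -0.056 (Tet3), where the median of all regions was -0.07. Leaving out 1 library gave ranges that crossed 0: at Aicda -0.52 to 0.15 (8.30 kb below), -0.082 to 0.62 (between Aicda and Apobec1) and -0.17 to 0.55 (inside Apobec1), and elsewhere -0.030 to 0.32 (Ly6c2), -0.029 to 0.16 (Bach2), -0.23 to 0.13 (Ebf1), -0.052 to 0.058 (Ezh2), -0.028 to 0.37 (Ccl22), -0.31 to 0.10 (Il10), -0.092 to 0.33 (Itgam), -0.11 to 0.073 (Ctla4) and -0.42 to 0.47 (Tet3).

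No list passed under the alternatives run for lists (merging of adjoining regions was not), and 19 list values changed direction. Their adjusted p was 0.882 (median of ratios), 0.880 (region totals) and 0.861 (RPKM) for growth, 0.890 (genes within 20 kb) and 0.780 (limma-voom) for myeloid, 0.890 (genes within 20 kb) and 0.941 (RPKM) for T and NK, and 0.980 (mean of at least 20) for TET enzymes. With 1 library left out, adjusted p ranged from 0.411 to 0.949 for B cell identity, 0.264 to 0.949 for LPS, 0.655 to 0.949 for T and NK, 0.655 to 0.979 for growth, 0.668 to 0.979 for myeloid and 0.234 to 0.987 for plasma cells. Tests by DESeq2 or edgeR were not run on the recovered reads, where limma-voom was used. GC or CpG corrections and the promoter and motif classes were not run, since no genome sequence was used. Depth limits weak regions most, at a median of 15 reads in WT replicate 2.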

Other observations

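The tests of region numbers per list, of the Tet2 region among regions of like strength, of X and Y reads, of region lengths and of a read ceiling were chosen after the results were seen, while limma's p for the Tet2 region comes from the planned fit over all regions. BATF regions were counted near the genes of each list and set against random gene lists. The lists were not compared with each other. Regulators of Aicda had 219 regions within 100 kb, against a median of 47 for 10000 random gene lists matched on the territory in which a region would be assigned to the gene, a 4.66-fold excess. LPS and NF-kappaB genes had 108 against 27, AP-1 and BATF partners 98 against 25, germinal centre genes 90 against 23, plasma cell genes 76 against 20, B cell identity genes 99 against 27, growth genes 97 against 29 and IL-4 and STAT6 genes 48 against 18. Each of these 8 lists had p = 0.0001, the smallest that the permutations can give. TET and DNA methylation enzymes had 33 against 18 (permutation test, Benjamini-Hochberg adjusted p = 0.0492), a 1.83-fold excess. Tet2 alone held 12 of the 33, and the test was not run without it. In regions of other than the 4 commonest lengths the excess was 1.90-fold (19 against 10), but with fewer regions it did not pass (permutation test, p = 0.0798). Class switch machinery (37 against 31, adjusted p = 0.292), T and NK markers (42 against 27, adjusted p = 0.07) and myeloid markers (24 against 19, adjusted p = 0.241) did not pass. So 9 of the 12 lists passed this test with all regions and 8 with regions of other lengths. That goes with the hypothesis that BATF regions gather near genes of many of the B cell and activation lists. Whether any factor that binds open chromatin would give the same excess was not tested.

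By single genes, Lpp had 40 regions, Bach2 33, Foxp1 30, Atxn1 27 and Akap13 26, all chosen after their values were seen. Unlike the list counts, these were not matched on territory, and a longer gene has more room for regions. Of 21907 genes considered, 10792 had at least 1 region. Bach2 stands in 3 of the 12 lists, so their excesses are not independent.

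Inside Tet2, a weak region on chromosome 3 (133470130 to 133470390), singled out after its values were seen, had normalised counts of 18 and 20 in WT and 10 and 1 in DKO, from 21, 14, 8 and 2 reads. Its log2 fold change was -2.09 (limma unadjusted p = 0.0271, adjusted p = 0.998). Of 5862 regions of like strength, this one included, 2 were as low in DKO. With that share the lowest of 6 such regions would be as low in 0.205% of draws. Tet2 holds 6 regions, but those with means of 21.25, 30.5 and 29.25 were stronger than this one (12.25) and not of like strength. The percentage therefore does not describe the regions inside Tet2 exactly. Another Tet2 region (133480747 to 133480961) had 13 and 16 in WT and 2 and 10 in DKO, but was 215 bp long, a length highest in WT replicate 2 in 82.4% of cases. The regions from 133497095 to 133497359 and from 133507380 to 133507622 had 27 and 24, and 15 and 13, in WT. In DKO they had 16 and 18, and 11 and 10 (limma unadjusted p = 0.108 and 0.465). The region from 133507380 to 133507622 was 243 bp long, a length highest in WT replicate 1 in 86.1% of cases. The regions from 133526364 to 133526697 and from 133542096 to 133542426 had 27 and 27, and 22 and 28, in WT. Their DKO values were 32 and 36, and 22 and 45. Inside Tet2, both DKO values thus lay below both WT values from 133470130 to 133507622 and not from 133526364 to 133542426. Outside the gene this also held from 133581669 to 133581917 (26 and 24 in WT, 11 and 19 in DKO, limma unadjusted p = 0.0565). It held as well from 133600386 to 133600671 (22 and 27, 20 and 15) and from 133626605 to 133626896 (106 and 108, 100 and 103). It did not hold in the outside regions starting at 133437024, 133583068 and 133625072. The pattern was therefore not confined to the gene body. Loss of the template in the floxed segment is a candidate explanation for the low values inside Tet2. It stays open, because the first region was picked for its low value and no region inside Tet2 passed the test. The floxed positions were not given in the sources used here.

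Chromosome Y reads followed the replicate number and not the genotype. The 15 Y regions held 540 reads in WT replicate 1 and 456 in DKO replicate 1, but 96 and 154 in the replicate 2 libraries, in the same order. Lower depth is argued against, since the replicate 2 libraries had at most 0.283 of the Y reads expected from their autosomal reads. X reads per autosomal read were 1.21 times higher in replicate 2 than in replicate 1 in WT (95% CI 1.18 to 1.25, counting error only) and 1.22 times in DKO, in line with male mice for replicate 1 and female mice for replicate 2, which would make the replicates of a genotype different animals. The labels used here give no sex, each genotype then had 1 library of either kind, and no effect of genotype was tested in this pattern. The replicate 2 libraries held 0 (WT) and 2 (DKO) reads in 9 of the Y regions. Nearly all of their 96 and 154 Y reads lay in the other Y regions, and the source of those reads was not tested.

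Regions of the 4 commonest lengths were each highest in a different library. Those of 215 bp (3180 regions) were highest in WT replicate 2 in 82.4% of cases, 227 bp (1544) in DKO replicate 1 in 92.0%, 243 bp (1984) in WT replicate 1 in 86.1% and 251 bp (3908) in DKO replicate 2 in 65.9%. Among the other 16293 regions no library led in more than 29.2%. That 4 libraries led the 4 lengths is the pattern itself, so it cannot test library depth. From 215 to 251 bp, the leading libraries had totals of 20866000, 32386000, 42967000 and 43981000 reads. The common lengths thus rose with the depth of the leading library, and a role of depth stays open. Genotype as the main cause is argued against, since the next highest library shared the genotype of the highest in 31.8% of regions. Libraries equal in depth and noise would give 33.3% by chance, and the regions of other lengths gave 29.5%. A smaller part of genotype was not tested. Peaks called at a fixed length in single libraries and then joined are a candidate explanation. Of the other regions 0.0798% were shorter than 215 bp, as joining needs, but a lower limit on peak length would give the same, so it stays open. These lengths make up 39.5% of the regions.

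The 3 strongest regions held nearly equal read numbers whatever the depth. They had 587, 583, 586 and 586 reads, 585, 581, 580 and 588 reads, and 575, 564, 566 and 570 reads in WT replicates 1 and 2 and DKO replicates 1 and 2. WT replicate 2 had 0.989 of the reads of WT replicate 1 in them, against 0.630 over all regions. A ceiling on the reads kept per position, such as removal of duplicates, is a candidate explanation. Reads per bp ran from 2.24 to 2.30 in these 3 regions over the 4 libraries. The highest in any other region was 0.823 of the highest in these 3. Since the 3 were picked for their read numbers, a lower value elsewhere decides little. The handling of duplicates is not given in the sources used here, so a ceiling stays open. No biological explanation was tested.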
